A study of Mus musculus with 6 samples.

How the data were processed

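Single-cell RNA sequencing of plasmacytoid dendritic cells sorted from mouse spleen (3 libraries) and bone marrow (3 libraries) was analysed. Libraries were made with the Single Cell 3′ v2 kit of 10x Genomics, per the labels. The authors deposited raw UMI counts per gene and cell in 1 table, without normalization: every value was a whole number. Cell Ranger, with no version given, R 3.4.0 and the mm10 genome build are named in the submitters' processing notes. The filters that left these barcodes and genes are not given in the sources used here; the barcode with the fewest genes had 101. Each cell was assigned to its library by the number at the end of its column name, which matches the sample number in the labels' descriptions. The table held 16992 genes, 16909 of them with a symbol. Gene positions are those of GENCODE vM21 on GRCm38 (mm10).

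The libraries held 3731, 2638 and 3196 barcodes in spleen and 2709, 3491 and 2912 in bone marrow, against 3000 cells per sample stated in the series. Barcodes with fewer than 500 genes (3378) or over 10% of UMIs from mitochondrial genes (825) were left out, which removed 3490 and kept 15187 cells. Scrublet was run per library, but called between 95.0% and 96.6% of the cells of the spleen libraries and at most 0.885% of those of the bone marrow libraries, so its calls were not used and no doublets were removed, contrary to the plan. Cells of other types (23) were set aside before clustering by a rule set after the data were seen.

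Cells were clustered with Leiden (resolution 1.0; 1000 variable genes, 30 principal components, 15 neighbours) in Python 3.11.15 with scanpy 1.11.5, leidenalg 0.10.2, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. Marker lists were fixed before the data were examined, and so were the gene lists, the tests, the rule for named genes and the other settings tried, except those named below. The thresholds that turned markers into names were set after the clusters were seen. A cycling cluster had at least 10 cell cycle genes raised. Of the others, a transitional-DC-like cluster had at least 5 of its markers raised and Siglech or Tcf4 at 100 CPM or more. No other list could hold more of its 10 leading genes. Of the rest, a pDC-like cluster had at least 15 of the pDC markers at 50 CPM or more. It was not named so where another list held several of its 10 leading genes and more than the pDC list. Cycling and transitional-DC-like clusters had 17 or 18 pDC markers at that level, so this count alone did not set the class apart. Clusters under 20 cells stayed unnamed. Names are rebuilt from these markers and can differ from those of the study. For the share of transitional-DC-like cells, the pDC-like and transitional-DC-like cells were clustered a second time without the genes called between tissues in the pDC-like class.

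UMI counts were summed per library over all kept cells and over the cells of each class. Tissues were compared with edgeR 4.0.16 (quasi-likelihood test, TMM, filterByExpr, Benjamini-Hochberg adjustment at 0.05) in R 4.3.3; a positive log2 fold change is higher in bone marrow. For the class difference and its interaction with tissue, each UMI was assigned at random with probability 0.5 to 1 of 2 parts, the first used for clustering and the second for the test, with library as a block. Clustering of the first part gave 719 transitional-DC-like cells, 665 of them among the 713 of the full clustering. Gene lists were tested with camera in limma 3.58.1 (preset correlation 0.01), with camera at an estimated correlation, and with fry. Shares were compared with exact permutation tests, for which 0.1 is the smallest p that 3 against 3 libraries allow; shares of cells with a UMI were taken after thinning each cell to 2000 UMIs. CPM values are means ± SD over libraries. Folds against a group at 0 use a floor of 3 counts over the group, which covers counting error only.

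Named genes were chosen by a fixed rule. It took, per comparison, the 10 largest rises and 10 largest falls among called genes with at least 20 CPM in the higher group and no overlap between libraries, without ribosomal, mitochondrial and unnamed genes; up to 4 called members of each list; and 11 fixed genes such as Siglech, Tcf4 and Zbtb46. An error in the test of overlap for the interaction was corrected after the results were seen, which changed the genes named there.

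Alternatives included DESeq2 1.42.0, RLE size factors, no filter on low counts, no cell filter, 1000 genes per cell, other resolutions except for the interaction, thinned cells, abundant genes left out, each library left out and the replicate number as a block. Others were added after the data were seen: a robust spread, limma on differences per library, the cells with the highest 2.5% of Scrublet scores left out, a pDC-like class without the clusters that hold a gene of another marker list among their leading genes, clusters compared by number, other resolutions for the interaction, and each library left out for the share of other cell types. Over all cells, same-numbered libraries of the tissues deviated together (correlations across genes 0.149, 0.302 and 0.381; 0.105, 0.249 and 0.262 in pDC-like cells). Libraries of unlike number had values from -0.353 to 0.195 over all cells and -0.266 to 0.0910 in pDC-like cells, and over all cells bone marrow 1 correlated better with spleen 2 (0.195) than with spleen 1. Every same-numbered pair exceeded 0.1, but so did spleen 2 with bone marrow 1 over all cells. The numbers were tried as pairs there, from the data and not from the labels, and these values do not establish the pairing. Replicate libraries of a tissue differed by more than counting noise (chi-square per degree of freedom between 2.95 and 8.08).

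The tests were checked on simulated counts (5 draws with 200 changed genes). For the comparison over all cells, the share of genes with a log2 change of 1 recovered was 90.1% and the share of false calls 7.54%; for the pDC-like class these were 86.6% and 8.85%, above the nominal 5% in both. For the transitional-DC-like class they were 69.3% and 4.25%, for the class difference 66.3% and 5.99% and for the interaction 25.7% and 5.47%.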

Results

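Plasmacytoid dendritic cells (pDCs) are specialised producers of type I interferon that arise in bone marrow and circulate to spleen and other lymphoid organs. The series compared single pDCs sorted from the spleen and the bone marrow of C57BL/6 mice, with 3 libraries per tissue. The series design names 3 mice and 3000 cells per sample, but not which mouse gave which library, so p-values measure the spread between libraries, whatever its source. The title of the series names heterogeneity and lineage of origin of pDCs as its question. Counts of unique molecular identifiers (UMIs) per gene and cell were analysed. The 6 libraries held 18677 barcodes and 78127481 UMIs over 16992 genes. Total UMIs were 12586003, 12004112 and 13309311 in spleen libraries 1 to 3, and 12360312, 16014764 and 11852979 in bone marrow libraries 1 to 3. After filtering, 7008 spleen cells and 8179 bone marrow cells remained. The median number of UMIs per kept cell was 5481, 5298 and 5092 in the spleen libraries and 4775, 4713 and 4488 in the bone marrow libraries, so depth was higher in every spleen library than in every bone marrow library.

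The kept cells fell into a large pDC-like class, a small transitional-DC-like class and a cycling class. Transitional dendritic cells are cells with features of both pDCs and conventional dendritic cells. The pDC-like class held 6662 spleen and 7137 bone marrow cells in 9 clusters with detectable pDC markers such as Siglech, a pDC surface lectin, and Tcf4, the transcription factor that maintains pDC identity. The transitional-DC-like class held 306 spleen and 407 bone marrow cells, led by Lgals3, which encodes galectin-3, by Sema4a and, in its mainly bone marrow cluster, by Cx3cr1, the fractalkine receptor. The top 10 genes of that cluster held 2 genes of the transitional DC list and 2 of the monocyte list, Lyz2 and Ms4a6c. Tissue and cluster were nearly the same split. Most spleen pDC-like cells lay in clusters 0, 2, 6 and 11 and most bone marrow pDC-like cells in clusters 1, 3, 4, 5 and 8. Nearly all transitional-DC-like cells of bone marrow lay in cluster 7 and most of those of spleen in cluster 10. Few cells were picked as other cell types. A rule that asked for at least 3 rarely detected markers of 1 list, or over 5% of UMIs from haemoglobin genes, picked 23 cells. They were 9 erythroid, 8 macrophage and 2 B cells, and 1 cell each of the T cell, natural killer or innate lymphoid, monocyte, and basophil or mast cell lists. The lists for type 1 conventional dendritic cells, precursor B cells, plasma cells, neutrophils, haematopoietic progenitors and stromal or endothelial cells picked 0 cells. This allows up to 0.0198% of kept cells that meet the rule, and sets no limit on the cell types themselves. The lists for type 2 conventional dendritic cells and megakaryocytes had only 2 rarely detected genes each and could pick none. These 23 cells made up 0.198% ± 0.0546 of spleen and 0.112% ± 0.0818 of bone marrow cells (SD, n = 3; exact permutation test, two-sided, p = 0.2). The erythroid cells made up 0.0990% ± 0.0160 and 0.0239% ± 0.0212 (exact permutation p = 0.1, the smallest that 3 against 3 libraries allow; adjusted p = 0.7 over 7 types).

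Sorted cells of the tissues differed in genes of the S phase and the G2 and M phase lists, and in genes of the MHC class II presentation and the immediate early and dissociation stress lists. All 25 measured S phase genes rose in bone marrow, and so did 24 of the 25 measured genes of G2 and M phase, with 1 lower; the counts were equal when adjusted over the list alone. Of the MHC class II list 13 of 14 fell (14 when adjusted over the list alone), and of the immediate early list 16 of 19 fell and 0 rose (16 when adjusted over the list alone). Over all kept cells, Rrm2, a subunit of ribonucleotide reductase, was at 26.6 ± 3.81 normalised UMI counts (CPM) in bone marrow and 0.927 ± 0.585 in spleen (mean ± SD, n = 3, here and below). Pclaf, a PCNA-binding protein, was at 108 ± 15.01 against 3.93 ± 1.54. The survivin gene Birc5 was at 29.5 ± 3.65 against 1.87 ± 1.60. Stmn1, which encodes the microtubule regulator stathmin, was at 302 ± 30.3 against 32.8 ± 3.77. Bcl2, an inhibitor of apoptosis, was higher in bone marrow as well, at 60.8 ± 6.80 against 10.5 ± 1.33. In spleen, the nuclear receptor gene Nr4a1 (ENSMUSG00000023034, chromosome 15, 101254269 to 101274795) was at 170.5 ± 7.61 against 0.769 ± 0.135. The chemokine gene Ccl4 was at 3602 ± 548 against 56.5 ± 11.6. Pmaip1, which encodes the pro-apoptotic protein NOXA, was at 149.97 ± 15.7 against 9.27 ± 0.795. In edgeR's quasi-likelihood test, 3712 of 11164 genes passed an adjusted p of 0.05, 1829 of them higher in bone marrow and 1883 higher in spleen. With every cell thinned to 2000 UMIs, 2170 genes passed. Of 5 fixed pDC genes, Siglech passed over all cells and the other 4 did not. Siglech (ENSMUSG00000051504, chromosome 7, 55768178 to 55778925) had a log2 fold change of bone marrow over spleen of -0.15 ± 0.03 (SE; adjusted p = 0.00191). The log2 fold change was -0.04 ± 0.04 for Tcf4 (adjusted p = 0.449), 0.04 ± 0.03 for Irf8 (0.239), 0.01 ± 0.04 for Spib (0.834) and -0.03 ± 0.03 for Bst2 (0.409). Bst2 had the other sign with thinned cells, at 0.02.

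The share of cells in which Mki67 or Top2a was seen was higher in every bone marrow library than in every spleen library, without passing a test. With every cell thinned to 2000 UMIs, which left out 163 spleen and 151 bone marrow cells, Mki67, the gene of the proliferation antigen Ki-67 (ENSMUSG00000031004, chromosome 7, 135689784 to 135716361), had a UMI in 1.33% ± 0.342 of bone marrow cells and in 0.118% ± 0.0964 of spleen cells. Top2a, which encodes topoisomerase II alpha, had a UMI in 3.405% ± 0.305 and 1.60% ± 0.415 of cells. The tissues were apart in all 6 libraries for both genes (exact permutation test, two-sided, p = 0.1 each, adjusted p = 0.114 over 8 genes), and 0.1 is the smallest p that 3 against 3 libraries allow. Without thinning the shares were 3.04% and 0.387% for Mki67 and 6.24% and 4.12% for Top2a. In thinned pDC-like cells, which were not counted as cycling, Mki67 was seen in 0.0768% of spleen and 0.272% of bone marrow cells and Top2a in 1.57% and 1.40%, at median depths of 5285 and 4583 UMIs before thinning. The cycling clusters, which were kept out of the pDC-like class, held 7.53% ± 1.05 of bone marrow and 0.273% ± 0.116 of spleen cells. They were formed on genes that differed between the tissues, so these shares only describe what was left out. Of the surface genes, Ly6c2 had a UMI in 79.7% ± 2.18 of bone marrow and 89.4% ± 1.60 of spleen cells and Ccr9 in 62.9% ± 2.32 and 72.1% ± 2.84. In the same order, Ly6d had a UMI in 93.6% ± 0.486 and 95.6% ± 1.39 and Siglech in 95.5% ± 0.241 and 96.7% ± 0.335 (exact permutation p = 0.1 and adjusted p = 0.114 for each gene, over 8 genes). Without thinning, these shares were 90.5% and 96.2% for Ly6c2, 83.0% and 91.1% for Ccr9, 97.8% and 98.3% for Ly6d and 99.3% and 99.2% for Siglech, the last with the opposite sign. The libraries of the tissues then overlapped for Ly6d (exact permutation p = 0.6) and Siglech (0.5). In thinned pDC-like cells the shares were 80.3% in bone marrow and 89.2% in spleen for Ly6c2, 68.7% and 74.3% for Ccr9, 94.95% and 98.1% for Ly6d and 97.7% and 98.4% for Siglech. In transitional-DC-like cells Ly6d (70.4% and 43.6%) and Siglech (77.4% and 62.4%) lay the other way. Ly6c2 was nearly level there (95.8% and 95.6%), and Ccr9 (23.6% and 25.5%) did not lie the other way. In cycling cells, 622 of bone marrow and 19 of spleen, Ly6d (94.4% and 89.5%), Siglech (82.6% and 68.4%) and Ccr9 (21.4% and 10.5%) lay the other way, and Ly6c2 (60.5% and 68.4%) did not. With 19 spleen cells these directions are uncertain. Shares by class were pooled over libraries and not tested. Of the cells of other types, 19 were deep enough to thin, at a median of 7195 UMIs; Siglech and Ly6d each had a UMI in 63.2% of them and Ly6c2 and Ccr9 each in 52.6%. Zbtb46, a transcription factor of conventional dendritic cells, had a UMI in 0.176% ± 0.0641 of bone marrow and 0.549% ± 0.120 of spleen cells (exact permutation p = 0.1, adjusted p = 0.114). Cx3cr1 had a UMI in 0.986% ± 0.146 and 0.805% ± 0.0526 (exact permutation p = 0.2, adjusted p = 0.2). In thinned pDC-like cells Zbtb46 was seen in 0.0286% of bone marrow and 0.107% of spleen cells (2 and 7 cells). Cx3cr1 was seen there in 0.157% and 0.0768% (11 and 5 cells). In transitional-DC-like cells the shares were 2.49% and 10.4% for Zbtb46 and 10.9% and 16.1% for Cx3cr1. In cycling cells they were 0.322% and 0% for Zbtb46 (2 and 0 cells) and 3.86% and 10.5% for Cx3cr1 (24 and 2 cells). Cx3cr1 thus lay the other way in transitional-DC-like cells. The 19 cycling cells of spleen were too few to give a direction for either gene. Without thinning, over all cells, the shares were 0.504% and 1.28% for Zbtb46 and 2.71% and 1.89% for Cx3cr1. The tissues were then apart for both genes (exact permutation p = 0.1 each).

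**Figure D1:**
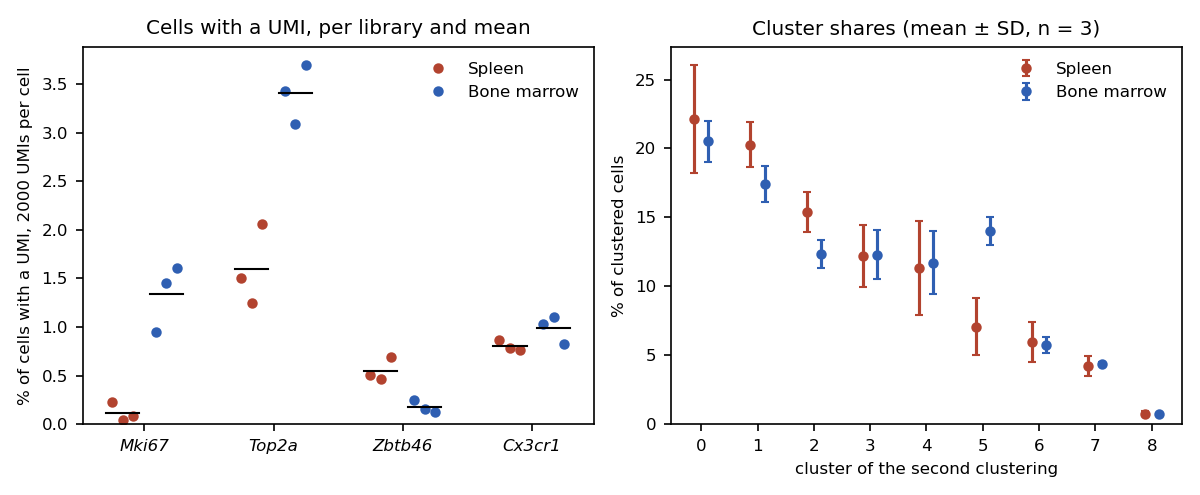
Left, percent of cells with at least 1 UMI of each gene after thinning each cell to 2000 UMIs, 1 point per library, with the mean as a line. Right, percent of the clustered cells in each cluster of the second clustering, as mean ± SD of 3 libraries per tissue. That clustering held pDC-like and transitional-DC-like cells only and was made without the genes called between tissues. Mki67 was seen in 1.33% of bone marrow and 0.118% of spleen cells, and cluster 5 held 14.0% of the clustered bone marrow and 7.08% of the clustered spleen cells.

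Within the pDC-like class, Nr4a1, Tent5c, Ccl4, Ccl3 and Pmaip1 were higher in spleen, and Sema4b, Id3, Sdc1, Bex6 and Bcl2 were higher in bone marrow. Nr4a1 was at 165 ± 7.83 CPM in spleen and 0.697 ± 0.367 in bone marrow, a log2 fold change of -7.95 ± 0.15 (edgeR adjusted p = 4.59e-10). Tent5c, which encodes a poly(A) polymerase, fell from 51.0 ± 1.64 to 0.503 ± 0.363, Ccl4 (ENSMUSG00000018930, chromosome 11, 83662584 to 83664683) from 3723 ± 538 to 65.1 ± 13.9, the chemokine gene Ccl3 from 162 ± 23.4 to 3.84 ± 1.64 and Pmaip1 from 136 ± 14.1 to 7.64 ± 1.19, each given as spleen to bone marrow. Bone marrow cells were higher in Sema4b, a semaphorin gene (214 ± 6.73 against 91.8 ± 5.29; adjusted p = 8.56e-08). They were also higher in Id3, an inhibitor of helix-loop-helix factors (70.2 ± 5.76 against 19.8 ± 4.18; adjusted p = 2.17e-06), and in Sdc1, which encodes syndecan-1 (43.5 ± 2.24 against 20.3 ± 0.794; adjusted p = 1.05e-06). Bex6 (29.0 ± 2.35 against 7.51 ± 1.07) and Bcl2 (ENSMUSG00000057329, chromosome 1, 106538178 to 106714274; 26.0 ± 2.03 against 8.22 ± 0.726) were higher too. Without clusters 0, 3, 4 and 5, which had leading genes from other marker lists, their log2 fold changes were 0.26 (adjusted p = 0.361) and 0.37 (0.300). Bex6 and Bcl2 were themselves leading genes of cluster 5, which held 215, 372 and 255 bone marrow but 7, 12 and 6 spleen cells. Leaving it out lowers both genes in bone marrow by construction, so this loss of calls says little about them. In clusters compared by number, Bex6 was called higher in bone marrow in 7 of 7 (0.95 to 2.67) and Bcl2 in 5 of 6 (0.82 to 2.53). In all, 2882 of 10901 genes passed, 1416 higher in bone marrow and 1466 higher in spleen, and 192 and 311 of them changed at least 2-fold. Thinned cells gave 1771.

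The class held clusters whose leading genes included genes of other lists. Cluster 0 had the monocyte-list gene Nr4a1 in its top 10 genes. Clusters 3 and 4 had the plasma cell gene Mzb1, and cluster 3 also had Sox4 of the precursor B cell list. Cluster 5 had S100a8, Sdc1 and Sox4. Clusters 0, 3, 4 and 5 each had 19 or 20 of the 20 pDC markers at 50 CPM or more. Their top 10 lists held 0 pDC markers, and so did those of clusters 2, 6, 8 and 11. Cells were therefore also compared by number in clusters 0 to 6 of a second clustering made without the genes that differed between the tissues, in which each cluster held cells of both tissues. Of 59 named genes called in the pooled class and tested in all 7 clusters, 56 had the same direction in all 7 and 32 were called in all 7. Nlrc5, Pgk1 and mt-Atp8 had the other direction in 1 cluster each. The genes were picked in the pooled class from largely the same cells and the same libraries, so this agreement is no independent check. Over all genes called in the pooled class, 93.0% to 98.7% per cluster had the same direction. Nr4a1 ranged from -10.15 to -6.82 across these clusters, H2-Ab1 from -2.53 to -0.92, and Sema4b from 0.81 to 1.46, with calls in all 7. The -2.53 of H2-Ab1 was that of cluster 5, and the other clusters lay between -1.24 and -0.92. With clusters 0, 3, 4 and 5 left out of the class, 1761 of 9849 genes passed, 1444 of them shared with the pooled class. Cluster 0, with 1301, 1167 and 1193 spleen cells, was left out for Nr4a1 alone, a gene far higher in spleen. The restricted class was thus not shown to be a purer pDC class. In that class Siglech had a log2 fold change of 0.12 (adjusted p = 0.0249) instead of -0.03 (adjusted p = 0.485) in the pooled class, and at a clustering resolution of 1.5 it had 0.02. Of the 86 named genes called in the pooled class, 78 were tested there, and 16 of these lost their calls. Among them were Ccr9 (log2 fold change -0.12, adjusted p = 0.184), Ly6c2 (-0.07, 0.335), Tlr7 (-0.22, 0.0805), Cd28 (-0.18, 0.263), Bex6, Bcl2, Bbc3, Cebpa, Gpi1, Lck, Mycl, Nlrc5, Pgk1, Rpl3l and mt-Nd1. By number, Ccr9, Ly6c2, Tlr7 and Cd28 were lower in bone marrow in all 7 clusters, with calls in 7 for Ly6c2 and Cd28, 5 for Tlr7 and 3 for Ccr9. With the replicate number as a block, Irf8 (log2 fold change 0.07, adjusted p = 0.0299) and Bst2 (0.07, 0.0370) passed in the pooled class, where without it their adjusted p was 0.109 and 0.0936.

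Genes of MHC class II presentation were lower in bone marrow pDC-like cells. Of 14 measured members, 13 fell and 1 did not pass (13 fell when adjusted over the list alone). H2-Ab1 (ENSMUSG00000073421, chromosome 17, 34257689 to 34269419), the beta chain of I-A, was at 1931 ± 45.0 against 4636 ± 318. H2-Eb1 was at 781 ± 15.4 against 1829 ± 134. H2-DMb2 was at 38.2 ± 3.05 against 140.2 ± 17.4. Cd83, a surface marker of activated dendritic cells, was at 0.685 ± 0.599 against 9.19 ± 1.48. The list's adjusted p was 2.56e-13 by camera with a preset correlation, and its adjusted p = 0.124 with an estimated correlation. Of the MHC class I list, 8 of 13 fell (8 when adjusted over the list alone), among them H2-K1 (1534 ± 148 against 2437 ± 184) and H2-D1 (2961 ± 213 against 3872 ± 202). This list had a camera adjusted p of 2.64e-05, and adjusted p = 0.326 with an estimated correlation.

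Genes of immediate early response and dissociation stress were lower in bone marrow too. Of 19 members, 15 fell, 1 rose and 3 did not pass (17 and 1 when adjusted over the list alone). Atf3, a stress-induced transcription factor, was at 0.152 ± 0.154 against 12.2 ± 1.90. Hspa1a, an inducible heat shock protein, was at 3.15 ± 2.25 against 36.0 ± 45.2, with spleen libraries far apart. Its call ended with a robust spread (adjusted p = 0.188) and without spleen replicate 3 (0.0517), bone marrow replicate 1 (0.0835) or bone marrow replicate 2 (0.0929). The list's adjusted p was 4.24e-11, and adjusted p = 0.0942 with an estimated correlation. Transcription factors of conventional dendritic cells fell in 8 of 11 members (8 when adjusted over the list alone): Irf4 (ENSMUSG00000021356, chromosome 13, 30749226 to 30766976) was at 6.07 ± 0.663 against 31.8 ± 5.33. Klf4 was at 19.7 ± 3.34 against 54.3 ± 18.7. Camera gave this list an adjusted p of 2.88e-05, and adjusted p = 0.0942 with an estimated correlation. Of the myeloid list, 6 of 14 fell (7 when adjusted over the list alone), with Lgals3 at 30.1 ± 3.12 against 51.5 ± 4.28. This list had a camera adjusted p of 0.00936, and adjusted p = 0.274 with an estimated correlation.

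The secretory pathway and unfolded protein response list held 10 members that fell and 1 that rose of 20 (11 and 1 when adjusted over the list alone). Ddit3, a stress-induced transcription factor, was at 18.9 ± 0.494 against 59.8 ± 6.59. Herpud1, a component of endoplasmic reticulum quality control, was at 250.1 ± 9.47 against 504 ± 16.1. Hspa5, the chaperone BiP, was at 494 ± 31.3 against 795 ± 73.6. By camera the list's adjusted p was 2.90e-04, and adjusted p = 0.418 with an estimated correlation. Ribosomal protein genes were higher in bone marrow: 60 of 86 rose and 1 fell (69 and 1 when adjusted over the list alone), by a median log2 fold change of 0.14, with Rpl39 at 3312 ± 73.6 against 2580.1 ± 229. Rps27 was at 366 ± 47.4 against 262 ± 19.99. Camera gave this list an adjusted p of 1.30e-18, and adjusted p = 0.0942 with an estimated correlation.

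The remaining lists did not pass by camera in pDC-like cells. Interferon-stimulated genes had 6 members higher in bone marrow, such as Parp14 (29.3 ± 4.32 against 17.9 ± 3.04), and 1 lower, Rsad2 (7.19 ± 0.394 against 13.9 ± 0.801), with the same counts when adjusted over the list alone. The list had an adjusted p of 0.147 by camera. Of the nucleic acid sensing list, 5 of 19 fell and 1 rose (the same when adjusted over the list alone), with the endosomal RNA receptor gene Tlr7 at 63.4 ± 5.70 against 89.4 ± 5.36. Slc15a4, a lysosomal transporter, was at 76.2 ± 19.1 against 122 ± 2.36. The list's camera adjusted p was 0.0640, and 0.0283 with the replicate block. Without the block it was 0.274 with an estimated correlation. In the chemokine receptor, adhesion and egress list 4 rose and 7 fell of 17 (4 and 8 when adjusted over the list alone), with the transcription factor gene Klf2 at 49.6 ± 10.8 against 148 ± 32.0. The adhesion molecule gene Icam1 was at 41.6 ± 1.98 against 107 ± 3.70. The list had an adjusted p of 0.142 by camera. The lymphoid list had 6 up and 3 down of 13 (7 and 3 when adjusted over the list alone), with the kinase gene Lck at 7.07 ± 1.08 against 1.61 ± 0.539. Ly6d (ENSMUSG00000034634, chromosome 15, 74762056 to 74763620) was at 3459.6 ± 89.6 against 4650.4 ± 203. The list's camera adjusted p was 0.201. The apoptosis list had 5 up and 6 down of 17 (the same when adjusted over the list alone), with the pro-apoptotic gene Bcl2l11 at 3.80 ± 0.700 against 13.4 ± 1.61. The list had an adjusted p of 0.699 by camera. The adjusted p of the other lists was 0.620 for mitochondrial transcripts (3 up and 2 down of 13) and 0.861 for pDC transcription factors (1 up, 2 down of 14). It was 0.123 for S phase (7 up, 2 down of 24), 0.320 for G2 and M phase (4 up, 1 down of 13), 0.867 for glycolysis (3 up, 3 down of 16) and 0.699 for nuclear genes of oxidative phosphorylation (2 up, 0 down of 19). Adjusted over the list alone, the numbers up and down were 3 and 3, 1 and 2, 8 and 2, 4 and 1, 5 and 4, and 2 and 0 in the same order. The median and mean log2 fold change had opposite signs for pDC transcription factors (0.05 and -0.04), apoptosis regulators (0.04 and -0.28) and glycolysis (-0.04 and 0.0015).

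**Figure D2:**
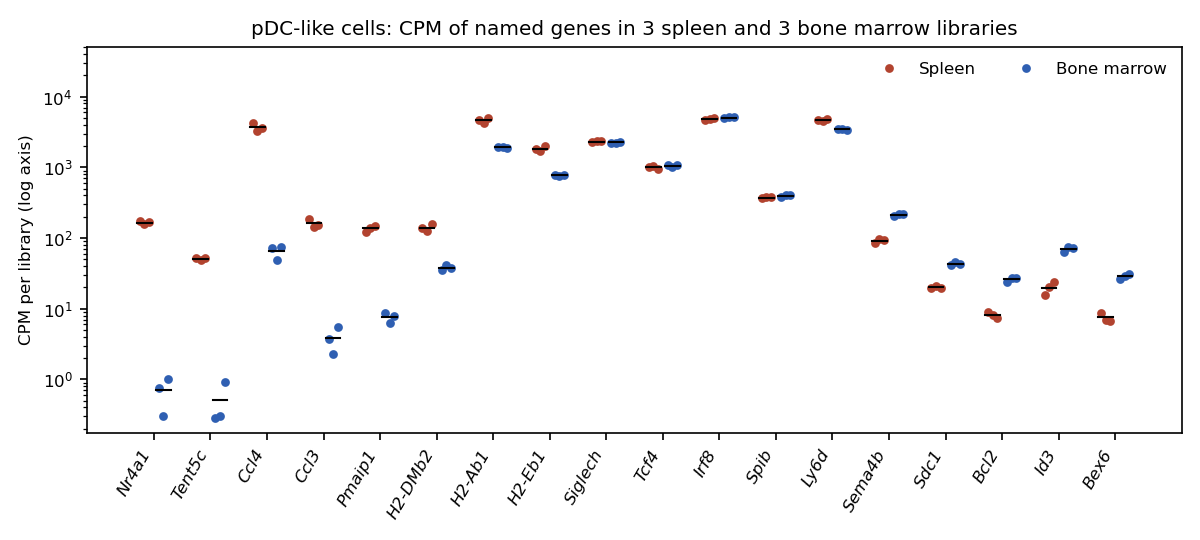
CPM of 18 named genes in the pDC-like class on a log axis, 1 point per library and the mean as a line, for 3 spleen and 3 bone marrow libraries. Nr4a1 lay at 165 ± 7.83 CPM in spleen and 0.697 ± 0.367 in bone marrow (mean ± SD), while Siglech, Tcf4, Irf8 and Spib lay close together in both tissues. Of the 20 pDC markers, 8 were called between the tissues in this class, Ccr9 and Ly6c2 among them. Siglech took the opposite sign at a resolution of 1.5 and without clusters 0, 3, 4 and 5.

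Transitional-DC-like cells of the tissues differed in genes of the MHC class II presentation and the immediate early and dissociation stress lists. Spleen cells were higher in Cd74, the MHC class II invariant chain (ENSMUSG00000024610, chromosome 18, 60803848 to 60812652), at 7654 ± 2357 against 759 ± 233, and in H2-Aa at 2156 ± 664 against 232 ± 76.4. Of the MHC class II list all 11 measured members fell in bone marrow (11 when adjusted over the list alone). The immediate early gene Fos was at 804 ± 8.08 in spleen against 96.1 ± 28.3 in bone marrow and Junb at 973 ± 175 against 110.2 ± 23.6. Of that list, 11 of 16 members fell and 0 rose (14 and 0 when adjusted over the list alone). Il1b, the interleukin 1 beta gene (ENSMUSG00000027398, chromosome 2, 129364570 to 129371139), had 171 UMIs in spleen and 0 in bone marrow, which puts bone marrow at least 72.3-fold lower against a floor of 3 counts over the tissue. The transcription factors Irf4 (84.1 ± 6.00 in spleen, 17.8 ± 2.31 in bone marrow), Relb (72.0 ± 6.82, 11.2 ± 4.44) and Zbtb46 (ENSMUSG00000027583, chromosome 2, 181387762 to 181459426; 49.7 ± 9.10, 11.5 ± 3.35) were higher in spleen as well, and 5 of 8 members of the conventional dendritic cell factor list fell in bone marrow (5 when adjusted over the list alone). Of 83 ribosomal protein genes 22 fell and 1 rose in bone marrow (28 and 4 when adjusted over the list alone; median log2 fold change -0.08), while in pDC-like cells most called members rose. The myeloid list had 3 up and 7 down of 15 (4 and 7 when adjusted over the list alone). Lists were counted in this class and not tested as sets.

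Bone marrow transitional-DC-like cells were higher in Ly6d (1118 ± 88.0 against 575 ± 107), a lymphocyte antigen gene, in Irf8 (4728 ± 128 against 3312 ± 472), an interferon regulatory factor, in Siglech (870.5 ± 90.5 against 600.4 ± 51.2) and in Sema4b (ENSMUSG00000030539, chromosome 7, 80186841 to 80226527; 49.2 ± 2.24 against 5.41 ± 3.58). The chemokine receptor gene Cxcr3 was at 34.5 ± 5.80 against 11.0 ± 5.81. Phgdh, which encodes an enzyme of serine synthesis, was at 80.8 ± 20.04 against 14.6 ± 2.88. Tcf4 did not pass (-0.04 ± 0.07, adjusted p = 0.778; 0.02 without bone marrow replicate 2). Spib passed (adjusted p = 0.0135) but lost its call in DESeq2, with thinned cells and without spleen replicate 1 or bone marrow replicate 2 or 3. In edgeR's test 736 of 6108 genes passed, 256 higher in bone marrow and 480 higher in spleen. DESeq2 called 339 and thinned cells 289. The call of Lyz2, at 125 ± 178 in bone marrow against 24.3 ± 8.64, rested on bone marrow replicate 2, without which its log2 fold change was -0.01. It also ended with a robust spread (adjusted p = 0.479) and without spleen replicate 1 (0.0709) or 3 (0.0761).

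**Figure D3:**
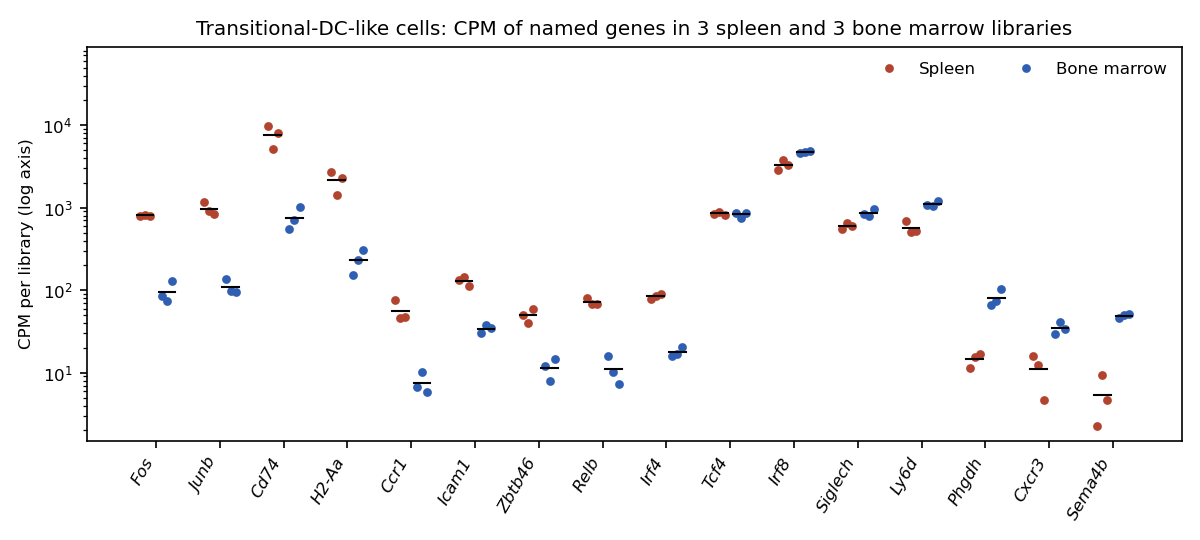
CPM of 16 named genes in the transitional-DC-like class on a log axis, 1 point per library and the mean as a line, for 3 spleen and 3 bone marrow libraries. Cd74 had a mean of 7654 ± 2357 CPM in spleen and 759 ± 233 in bone marrow, and Sema4b 49.2 ± 2.24 in bone marrow against 5.41 ± 3.58 in spleen (± SD).

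The share of transitional-DC-like cells was compared in a second clustering made without the genes called between tissues in the pDC-like class. Those genes included 7 of the 15 transitional DC markers and 8 of the 20 pDC markers. In that clustering, transitional-DC-like cells made up 4.46% ± 0.0930 of the bone marrow and 4.29% ± 0.767 of the spleen cells named pDC-like or transitional-DC-like (exact permutation test, two-sided, p = 1.0). Cycling cells, 7.53% of kept bone marrow and 0.273% of kept spleen cells, were outside these totals. The shares are therefore not shares of all kept cells. The difference of 0.166 points was smaller than the spread between spleen libraries. Without spleen replicate 1 the difference was -0.276 points, and it was 0.530 points at a resolution of 0.5 and 0.341 points with 2000 variable genes. With the called genes kept in the clustering it was 0.960 points and the libraries of the tissues did not overlap, at 5.27% to 5.57% in bone marrow and 3.56% to 5.03% in spleen (exact permutation p = 0.1, the smallest that 3 against 3 libraries allow).

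The transitional-DC-like cells differed from pDC-like cells in the same library by higher myeloid and conventional dendritic cell genes and lower lymphoid genes. These values came from held-out UMIs that took no part in the clustering. Sema4a (ENSMUSG00000028064, chromosome 3, 88435959 to 88461182) was at 103 ± 41.4 CPM in transitional-DC-like and 0.777 ± 0.502 in pDC-like cells. Zbtb46 was at 35.1 ± 25.8 against 0.267 ± 0.0966. Csf1r, the receptor of a macrophage growth factor, was at 27.4 ± 8.24 against 0.719 ± 0.457 (mean ± SD over 6 libraries). In pDC-like cells Ccr9, a homing receptor gene, was at 774 ± 96.2 against 129 ± 18.9. Siglech was at 2304 ± 57.5 against 678 ± 155. Ly6d was at 4135 ± 634 against 892 ± 372. Tlr7 was at 74.5 ± 13.9 against 12.0 ± 5.25 and Dntt, the terminal transferase gene (ENSMUSG00000025014, chromosome 19, 41029275 to 41059525), at 156 ± 21.5 against 5.39 ± 4.94. Tcf4 (-0.36 ± 0.06) and Irf8 (-0.39 ± 0.06) were lower by less, as log2 fold changes of transitional-DC-like over pDC-like cells with SE, and Ly6c2 was higher (0.86 ± 0.05). Id2, a gene of the transitional DC list, had 2 held-out UMIs in transitional-DC-like and 302 in pDC-like cells. In CPM of the summed UMIs these were 0.966, under the floor of 1.45, and 8.77, a ratio of 0.110 (95% exact interval 0.0133 to 0.401, counting error only). Ccr9, Ly6d, Dntt, Ly6c2 and Id2 were features of the clustering, so their values only describe the classes. Sema4a, Zbtb46, Csf1r, Siglech, Tlr7, Tcf4 and Irf8 were not features. Of these, Zbtb46 was a transitional DC marker, and Siglech, Tcf4 and Irf8 were pDC markers, used to name the clusters. The class differences of these markers are therefore not independent of the names. In edgeR's test with library as a block, 2656 of 9560 genes passed, 1297 higher in transitional-DC-like and 1359 higher in pDC-like cells.

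Of the myeloid list 10 of 16 rose and 5 fell (10 and 5 when adjusted over the list alone), with Klf4 at 224 ± 46.1 against 38.6 ± 21.8. The list's camera adjusted p was 8.61e-04. Of the conventional dendritic cell factors 6 of 9 rose and 1 fell (7 and 1 when adjusted over the list alone), with Spi1, which encodes PU.1, at 516 ± 144 against 94.1 ± 7.13. The list had an adjusted p of 2.55e-04 by camera. Glycolysis genes rose in 9 of 16 (11 when adjusted over the list alone), with the hexokinase gene Hk2 at 23.4 ± 11.2 against 4.21 ± 1.73. The list's camera adjusted p was 1.08e-04. The lymphoid list fell in 7 of 12 and rose in 1 (9 and 1 when adjusted over the list alone), with the interleukin receptor gene Il7r at 41.4 ± 8.56 against 144 ± 9.33. The list had an adjusted p of 1.08e-04 by camera. Mitochondrial transcripts fell in 12 of 13 (the same count when adjusted over the list alone), with mt-Nd1 at 2250.1 ± 92.9 against 3592 ± 236. The list's camera adjusted p was 2.86e-15. These 5 lists kept their calls with an estimated correlation. Klf4, Spi1, Il7r and mt-Nd1 were features of the clustering and only describe the classes, while Hk2 was not a feature. The list tests of the class difference, here and below, kept features and naming markers as members, and none was run without them. Calls of lists that hold such genes therefore partly restate how the classes were made.

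Another 6 lists passed by camera only at the preset correlation. The secretory list fell in 11 of 20 members (15 when adjusted over the list alone), with Xbp1, a regulator of secretory cells, at 157 ± 28.2 against 382 ± 48.5. This list had a camera adjusted p of 3.68e-07, and adjusted p = 0.0748 with an estimated correlation. The MHC class I list fell in 6 of 13 (6 when adjusted over the list alone). By camera the list's adjusted p was 2.90e-04, and adjusted p = 0.0622 with an estimated correlation. Interferon-stimulated genes fell in 9 of 24 and rose in 1 (10 and 1 when adjusted over the list alone). Camera gave this list an adjusted p of 0.0212, and adjusted p = 0.282 with an estimated correlation. The pDC transcription factors fell in 8 of 14 and rose in 3 (the same when adjusted over the list alone). This list had a camera adjusted p of 0.0474, and adjusted p = 0.230 with an estimated correlation. Ribosomal protein genes rose in 37 of 84 and fell in 7 (42 and 9 when adjusted over the list alone). By camera the list's adjusted p was 2.74e-04, and adjusted p = 0.549 with an estimated correlation. Apoptosis regulators rose in 4 of 16 (4 when adjusted over the list alone). Camera gave this list an adjusted p of 0.0474, and adjusted p = 0.193 with an estimated correlation. The lists for MHC class II (0.540, 5 up and 7 down of 14) and nucleic acid sensing (0.0891, 3 up and 7 down of 18) did not pass by camera at the adjusted p given. Nor did those for chemokine receptors (0.0623, 4 up and 10 down of 18), S phase (0.341, 2 up and 1 down of 20), G2 and M phase (0.0891, 4 up and 1 down of 8), immediate early genes (0.221, 7 up and 7 down of 18) and oxidative phosphorylation (0.749, 6 up and 1 down of 19). Adjusted over the list alone, the numbers up and down were 5 and 7, 4 and 8, 4 and 11, 2 and 1, 5 and 1, 7 and 8, and 6 and 3 in the same order. For oxidative phosphorylation the median log2 fold change was -0.02 and the mean 0.05.

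**Figure D4:**
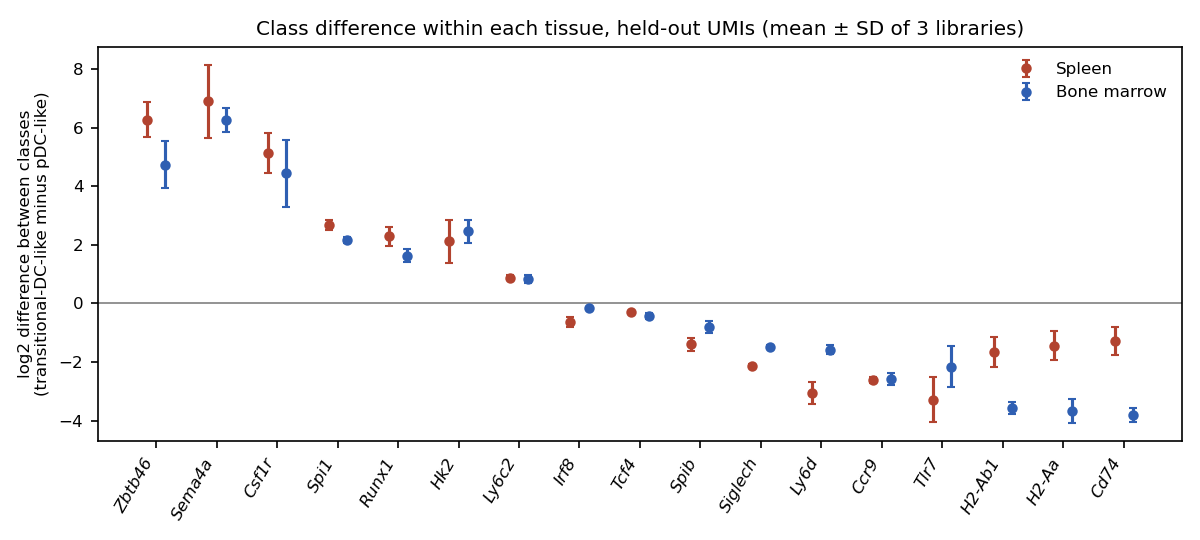
log2 difference of held-out CPM between transitional-DC-like and pDC-like cells of the same library, as mean ± SD of 3 libraries per tissue. Zbtb46, Sema4a and Csf1r lay above 0 in both tissues, and Ccr9, Tlr7 and Cd74 below 0. Ccr9 and Cd74 were features of the clustering, and Zbtb46 and Ccr9 were markers used to name the clusters.

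The class difference was compared between tissues with an interaction term. Of 14 MHC class II genes, 4 had a more negative class difference in bone marrow and 10 did not pass (7 passed when adjusted over the list alone). Cd74 had a log2 class difference of -3.80 ± 0.25 in bone marrow and -1.27 ± 0.47 in spleen (SD, n = 3), and H2-Aa -3.67 ± 0.41 and -1.44 ± 0.49. Ly6d and Siglech differed less between classes in bone marrow, at -1.58 ± 0.16 and -3.05 ± 0.38 for Ly6d and -1.47 ± 0.04 and -2.12 ± 0.07 for Siglech. Irf8 had -0.15 ± 0.04 and -0.64 ± 0.18, and Cxcr3 -1.88 ± 0.52 and -4.17 ± 0.84. Of these genes, Cd74, H2-Aa and Ly6d were features of the clustering, and Siglech and Irf8 were pDC markers used to name the clusters. Ccr9 (adjusted p = 0.962) and Ly6c2 (0.880) did not pass. Of 84 ribosomal protein genes, 54 had a smaller and 1 a larger value in bone marrow (67 and 2 when adjusted over the list alone). In the edgeR fit 300 of 9560 genes passed, 127 with a larger and 173 with a smaller value in bone marrow. The fit estimated an infinite number of prior degrees of freedom, so its p-values rested on a spread set almost wholly by the trend over genes. With limma on the class differences per library, 131 genes passed, 128 of them shared, and DESeq2 called 119. By limma the adjusted p was 1.14e-04 for Cd74, 5.98e-04 for H2-Aa, 5.98e-04 for Ly6d, 5.26e-04 for Siglech, 0.00699 for Irf8 and 0.0219 for Cxcr3. With a robust spread, all 4 MHC class II genes lost their calls in edgeR: Cd74 (adjusted p = 0.0669), H2-Aa (0.145), H2-Ab1 (0.187) and H2-Eb1 (0.170).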

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

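All tests of explanations in this part were chosen after the results were seen, except the test of doublets, and so were the limma, robust and resolution alternatives for the interaction and the clusters compared by number.

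The class difference differed between tissues for 300 genes in edgeR's interaction test, which estimated infinite prior degrees of freedom; DESeq2 called 119 and limma 131. The interaction log2 values were -2.51 for Cd74, -2.19 for H2-Aa, -1.91 for H2-Ab1 and -2.39 for H2-Eb1, so these MHC class II genes had a more negative class difference in bone marrow. They were 1.49 for Ly6d, 0.64 for Siglech, 0.47 for Irf8 and 0.57 for Spib. By limma the adjusted p of Spib was 0.0849, and by DESeq2 0.0979. With a robust spread the adjusted p was 0.0669 for Cd74, 0.145 for H2-Aa, 0.187 for H2-Ab1 and 0.170 for H2-Eb1.

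For the MHC class II genes, the different clusters that make up the class in the tissues cannot be told apart from the tissue. With 1 cluster for the class the median interaction of the 4 genes was -2.28 against -2.29, but that setting kept nearly the same cells (695 against 719). The second clustering was made without these genes. In its 1 transitional-DC-like cluster their log2 fold changes ran from -3.35 for Cd74 to -2.74 for H2-Ab1. In pDC-like cluster 5 they ran from -2.53 for H2-Ab1 to -2.38 for Cd74, and in the other pDC-like clusters from -1.24 to -0.87. A large gap was thus also present in 1 pDC-like cluster. Of the 627 cells of the transitional-DC-like cluster, 607 were those of the class, so neither setting decides. Free RNA from other spleen cells also stayed open: it would add about the same CPM to both classes; the median ratio of the spleen minus bone marrow differences, transitional-DC-like over pDC-like, was 0.673, close to the bound of that test, with 0.809 for Cd74 and 0.544 for H2-Ab1, whose libraries were apart between the classes. A difference between the tissues themselves stays open, untested.

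Immediate early genes were higher in spleen pDC-like cells. Free RNA from other cells was argued against as the whole cause for part of the list: 53.3% of the 15 members called higher in spleen (8) differed over 1.5 times between the classes in spleen with libraries apart, and 53.3% did in the spleen excess over bone marrow. Both shares lay just above the bound of that test, and some ratios of transitional-DC-like over pDC-like cells lay near the cut. In spleen they were 1.51 for Hspa8 and 1.53 for Nr4a1, and in the excess 1.53 for Nr4a1 and 1.54 for Junb. For the other 7 in each test free RNA stays open, and so it does for Hspa8, whose excess was nearly level between the classes (ratio 1.09). Handling stress during dissociation may contribute: the 5 heat shock members had a median log2 fold change of -0.60, with 4 called, although Hspa1a rested on few libraries. Handling and tissue were confounded, so a difference between tissues also stays open.

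More cells were counted as cycling in bone marrow. A difference in depth was argued against for Mki67, since it would raise the share of cells with a UMI in the deeper tissue: the median of UMIs per cell was higher by 632 in spleen (mean over libraries, tissues apart), while 3.04% of bone marrow and 0.387% of spleen cells had a UMI of Mki67 without thinning. Without the highest Scrublet scores the difference in the share of cycling cells was 7.30 percentage points, against 7.25 with them, which met the bound written before for no effect of doublets. That bound was not used, because Scrublet called nearly all spleen cells and only 6 of the 643 cycling cells were left out, so the test says nothing about doublets. A difference between tissues stays open.

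Barcodes under 500 genes, which entered only the alternative with no cell filter, held haemoglobin UMIs. They made up 0.0190%, 11.3% and 15.4% of UMIs in those barcodes of spleen libraries 1, 2 and 3, and 1.99%, 0.0166% and 2.03% in bone marrow libraries 1, 2 and 3.

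Splits of the 6 libraries into 3 and 3 number 10, the real one included, too few for a share under 0.05. The real split gave 3712 genes over all cells, 2882 in the pDC-like class, 736 in the transitional-DC-like class and 300 for the interaction, each in 1 of 10 splits, and the highest other gave 0, 0, 0 and 1. For gene lists 2 of 10 splits gave 7 lists, the real one among them. Among the 4 splits that part every pair of same-numbered libraries, the highest other gave 0 genes over all cells and in pDC-like cells and 5 lists, and those splits mix the tissues within each group. For the class difference, with the classes swapped within libraries, 1 of 32 splits gave as many genes (2656, highest other 7) and 1 of 32 as many lists (11, highest other 9). The classes came from 1 clustering of all libraries, which lines them up, so these splits say nothing about chance.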

How the results depend on the processing

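The alternatives with a robust spread, limma, clusters of other lists left out, clusters compared by number, the highest Scrublet scores left out, resolutions for the interaction and libraries left out for the share of other cell types were chosen after seeing the data; the others were planned. Keeping the doublets equals the reported result, since none were removed, and has no value of its own. With cells thinned to 2000 UMIs, 2170 genes passed over all cells, 1771 in the pDC-like class and 289 in the transitional-DC-like class; fewer UMIs and fewer genes entered those tests. DESeq2 called 339 genes in the transitional-DC-like class and 119 for the interaction, and limma 131 for the interaction. The pDC-like class without the clusters led by other lists gave 1761. An estimated correlation left 0 of 7 gene lists for the tissue difference and 5 of 11 for the class difference; fry called 11 and camera over all cells 12 for the tissue difference. The cause was not tested for these, except where fewer counts were used. Without 1 library, counts ranged from 2784 to 3464 over all cells, 2016 to 2684 in the pDC-like class, 509 to 705 in the transitional-DC-like class, 2285 to 2456 for the class difference, 200 to 262 for the interaction, 7 to 8 lists for the tissue difference and 9 to 13 for the class difference.

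Some values took the other sign. Bst2 over all cells had a log2 fold change of 0.0214 with thinned cells, Siglech in the pDC-like class 0.0184 at resolution 1.5 and 0.12 without the clusters led by other lists, and Rfc2 in the transitional-DC-like class -0.35 with thinned cells and -0.0234 without the highest Scrublet scores. The share of cells with a UMI of Siglech differed by 0.0992 points without thinning. Without 1 library, log2 values ranged over all cells from -0.152 to 0.0177 for Id2 and -0.000981 to 0.0314 for Spib. In the transitional-DC-like class they ranged from -0.0776 to 0.0233 for Tcf4, -0.00941 to 3.00 for Lyz2 and -0.114 to 0.161 for Rfc2. In the interaction they ranged from -0.0516 to 0.155 for Ccr9, -0.0936 to 0.0369 for Ly6c2 and -0.196 to 0.0158 for Rfc2. The share of transitional-DC-like cells ranged from -0.276 to 0.408 points. The ranges for cells with a UMI were -0.417 to -0.305 for Zbtb46, 0.122 to 0.263 for Cx3cr1, -10.5 to -8.38 for Ly6c2, -10.5 to -7.57 for Ccr9, -2.56 to -1.25 for Ly6d, -1.32 to -1.01 for Siglech, 1.08 to 1.41 for Mki67 and 1.63 to 2.03 for Top2a; that for other cell types was -0.131 to -0.0510. The cause was not tested.

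With the replicate number as a block, 4046 genes passed over all cells, 3365 in the pDC-like class, 701 in the transitional-DC-like class and 8 lists; the share of transitional-DC-like cells had an exact sign-flip p of 1.0, where 0.25 is the smallest. It added Irf8, Bst2 and the nucleic acid sensing list in the pDC-like class and changed no other call of a named gene over all cells or there. In transitional-DC-like cells, where same-numbered libraries did not deviate together (-0.0460, 0.0552 and 0.0865), Bid, Ddit3 and Ldha did not pass under it. Of the named called genes that every alternative run could test, 67 of 77 over all cells, 51 of 68 in the pDC-like class, 33 of 47 in the transitional-DC-like class, 79 of 92 for the class difference and 10 of 40 for the interaction kept their calls under all of them.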

Other observations

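The shares given here were picked for description after the data were seen. They are shares of the pDC-like and transitional-DC-like cells of the first clustering, without cycling cells. In the second clustering, made without the genes called between tissues, cluster 5 was led by Bcl2, Bex6, Sdc1 and Sox4. It held 14.0% ± 1.02 of bone marrow and 7.08% ± 2.07 of spleen cells (SD, n = 3; exact permutation test, two-sided, p = 0.1, the smallest that 3 against 3 libraries allow; adjusted p = 0.3 over 9 clusters). Clusters 1 and 2 had the same exact p and lay the other way, at 17.4% ± 1.30 against 20.3% ± 1.65 and 12.4% ± 1.03 against 15.4% ± 1.47, so none of the 3 passed. Cluster 6 was led by interferon-stimulated genes such as Isg15 and Rsad2, and held 5.73% ± 0.574 of bone marrow and 5.96% ± 1.46 of spleen cells (exact permutation p = 1.0). Cluster 8, 107 cells led by S100a8, S100a9 and Retnlg of the neutrophil list, stayed unnamed and held 0.713% ± 0.0522 and 0.752% ± 0.182 (exact permutation p = 0.9). Its cells came from the pDC-like and transitional-DC-like classes of the first clustering and were not removed from the sums of those classes. In the first clustering at a resolution of 1.5, a cluster of 647 cells led by S100a8 and S100a9 was unnamed and so outside the pDC-like class of that setting.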
